A study of Homo sapiens with 3 samples.

How the data were processed

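RNA was measured in 192 culture wells of senescent IMR-90 fibroblasts, 8 wells in each of 24 groups given by 4 treatments and 6 times. Per the labels the cells were lysed in the wells, RNA was reverse transcribed with a barcode for each well, and the wells were then pooled for tagmentation, 64 to a library, so that the 0 and 2 h, the 4 and 8 h and the 12 and 24 h wells each shared 1 library. The deposited files hold counts, as raw whole numbers for each gene symbol and well with no normalization. The labels list STAR 2.4.2a and the genome build hg38, and the counting tool, the annotation, any gene filter and whether molecular identifiers were counted are not stated. Each file lists the genes with at least 1 count in it, 17100, 17535 and 17942 genes in time order and 19204 in their union. The files list no mitochondrially encoded gene (0 with an MT- symbol). Treatment, time and replicate number were taken from the column names, which gave a group to all 192 wells.

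Wells were kept where their total reached 10% of their pool's median, which left 185 wells of 22506 to 684392 counts. The 7 wells left out held 113 to 17461 counts. Genes were kept by edgeR's filterByExpr on the 24 groups, which left 7901. Normalization was by TMM, and 1 quasi-likelihood model with a coefficient for each group was fitted in edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with robust estimation, at a common biological coefficient of variation of 18%. Every contrast was taken between wells of 1 pool or averaged over such contrasts, so that a difference between pools cancelled. The contrasts were GA vs con, IL6 vs con and IL6andGA vs IL6 at each time and averaged over 2, 4, 8, 12 and 24 h, the interaction of GA and IL6 over these times, the later against the earlier time of a pool in con, and the change of the GA effect between these times. Tests were two-sided and p-values were adjusted by Benjamini and Hochberg over the 7901 genes of a contrast, with a threshold of 0.05. Errors of log2 fold changes are standard errors from the fit, and CPM values of tested genes are counts scaled by the effective (TMM) library size of each well over the genes kept, given as the mean and SD over wells. CPM over all wells, CPM of genes under the filter and CPM of the IL6 receptor genes were scaled by the total counts of the wells, without TMM.

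The choices of model, filter, contrasts, gene lists, named genes and alternatives were made before the data were examined. The 35 gene lists hold 775 entries, of which 729 matched a symbol in the files, 17 of them through an older symbol. The 27 lists with at least 5 tested genes were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with a correlation estimated for each list. The report names the lists that pass with both, and gives the adjusted p with an estimated correlation where a list passes only with the preset one. Members were counted over all genes tested and adjusted over the list alone. The 8 lists not tested were the metallothioneins, mitochondrially encoded, aryl hydrocarbon receptor, and gap junction and 11β-hydroxysteroid dehydrogenase genes and the epithelial, endothelial, blood and immune, and mural and mesothelial markers.

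The rule for named genes took, for each treatment comparison, the 10 largest rises and 10 largest falls over the mean among genes past the threshold with 1 sign at all 5 times and at least 5 CPM. It added 16 SASP, growth arrest and IL6 pathway genes whatever their result, up to 4 members with the smallest p in each list that passed, and the 3 largest rises and falls at each time. The report quotes a part of these genes. Where it quotes a gene that the rule named at 1 time or in 1 arm at another time or in the other arm (ABCA1, ASNS, ATF4, BNIP3, CXCL8, DDIT4, FGF7, GDF15, IFI6, IGFBP5, PCK2, TNFRSF11B and TRIB3), where it names the few members of a list that passed, and where it names genes that moved in opposite directions in the arms or at 12 h and 24 h, the choice was made after their values were seen. The tests of the difference in GA effect between the arms at 12 h and 24 h alone were also chosen after the data were seen.

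IL6, IL1A, IL1B, CXCL1, SOCS3 and HSD11B1 were under the count filter and are given as counts. SOCS3 and CXCL1 were compared between groups at each time by exact permutation tests of the CPM of the wells, two-sided and adjusted over 36 tests. The limit that 0 counts allow was taken as 3 counts of the summed total. Replicate numbers were not taken as pairs, since the correlation between same-numbered wells of different treatments, after the group means were removed, averaged 0.0207 over 269 pairs and ranged down to -0.624. Transcript lengths came from GENCODE release 29 and were found for 7616 of the 7901 genes (96.4%). A well's length slope was that of its log2 CPM on log2 length, after each gene's mean over the pool was subtracted.

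The model was tested on simulated counts drawn at the depths of the wells, with 7422 genes tested in 24 groups. Of genes with a true 2-fold change between GA and con 29 of 45 (64.4%) were recovered at 24 h, 62.2% at 12 h, 66.7% at 2 h, 71.1% at 4 h and 22.2% at 8 h, and of those with a 4-fold change 97.9%, 93.8%, 95.8%, 95.8% and 54.2%. Of 7232 unchanged genes 21 or fewer were called in any contrast, but as a share of the genes called these were 11.5% over the mean, 5.15% at 2 h, 5.23% at 4 h, 15.9% at 8 h, 2.46% at 12 h and 2.88% at 24 h. In these simulated counts the threshold of 5% was thus not held over the mean or at 8 h, and was slightly exceeded at 2 h and 4 h. The simulation gave each gene 1 spread in all groups. The real 2 h wells may hold more structure, as a random split of the IL6andGA and IL6 wells gave 361 genes and the real split 1. The simulated shares at 2 h do not cover that. The list test found the 1 list that had been raised and 0 of 20 random lists. Genes were drawn independently of each other there. The simulation thus cannot decide whether the preset correlation holds the error rate of the list test in real wells.

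Alternatives changed 1 choice at a time: RLE size factors in place of TMM, the DESeq2 1.42.0 Wald test, no low-count filter, estimation without the robust option, all 192 wells kept, only wells with 50% or more of the pool median, each file fitted alone, the replicate number as a block, and each well left out in turn in groups of 5 wells. Means without 2 h, without 8 h or without both, and each well's length slope as a covariate, were added after seeing the data. For each gene count 39 random splits of the wells into groups of the same sizes were drawn with a fixed seed and compared with the real split, 40 in all. The GA effects with and without IL6 were correlated across genes, beside 100 permutations of the well labels. The permutations used differences of mean log2 CPM, and the correlation was also given in that measure.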

Results

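The data were RNA counts from IMR-90 cells, a line of human lung fibroblasts, taken to replicative senescence, the lasting growth arrest that follows repeated division. The cells were cultured with or without 18β-glycyrrhetinic acid (18β-GA, called GA here), the aglycone of the licorice saponin glycyrrhizin and a known inhibitor of 11β-hydroxysteroid dehydrogenases and gap junctions, at 50 µM. Both arms were also run with interleukin 6 (IL6) at 50 ng per ml, which made 4 treatments (con, GA, IL6 and IL6andGA) at 0, 2, 4, 8, 12 and 24 h. The submitters' stated purpose was to follow GA's effect on the senescence-associated secretory phenotype (SASP), the cytokines, proteases and growth factors that senescent cells release. Each of the 24 groups had 8 wells, and the 192 wells were sequenced in 3 pools of 64. These held the 0 and 2 h, the 4 and 8 h and the 12 and 24 h wells.

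Total counts per well ran from 113 to 684392. Medians were 324636 in the 0 and 2 h pool, 204982 in the 4 and 8 h pool and 314850 in the 12 and 24 h pool. The 7 wells under 10% of their pool's median were left out. They were GA 8 h replicates 1, 3 and 8, IL6andGA 8 h replicates 1, 2 and 3, and con 12 h replicate 1. The 185 wells kept held 22506 to 684392 counts, and 7901 genes were tested. The 8 h wells were the shallowest, with median totals among the wells kept of 131209 in con, 29233 in GA, 51391 in IL6 and 80307 in IL6andGA, against 392297, 334921, 373364 and 317856 at 24 h. No source says whether the wells were separate cultures, so p-values measure the spread between wells, which may be technical. The model estimated 1 spread per gene over all 24 groups, so the p-values of 1 time also rest on the spread at the others. With each pool fitted alone GA vs con gave 42 genes in place of 207 at 0 h and 565 in place of 360 at 12 h.

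**Figure D1:**
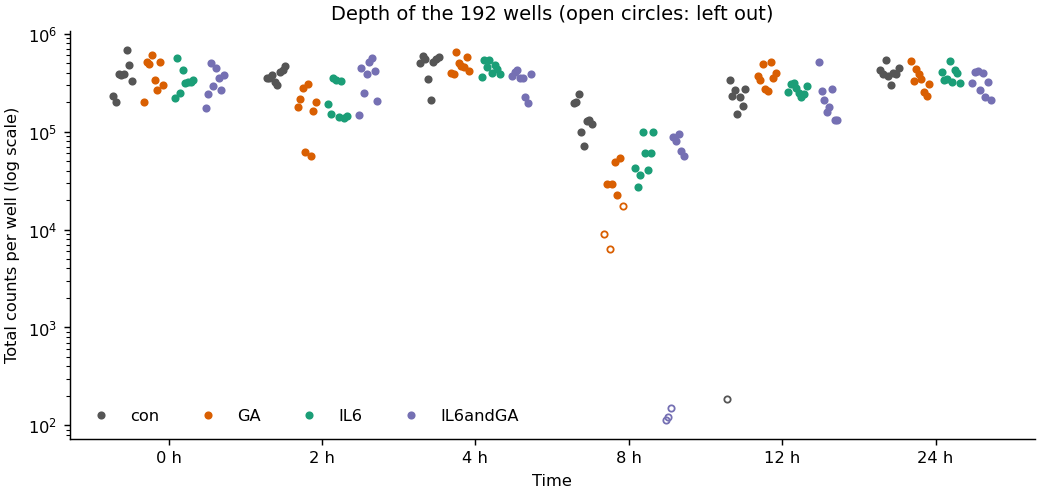
Total counts of each of the 192 wells (points, log scale) by time in h and treatment, with the 7 wells left out drawn as open circles. The 8 h wells lie lowest, and the wells left out at 8 h and 12 h lie between 113 and 17461 counts.

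The best known SASP cytokines had few counts in these libraries. IL6 itself had 26 counts over the 185 wells (0.453 CPM, here counts scaled by the summed totals of the wells), IL1A, an upstream SASP trigger, had 25 (0.436) and IL1B had 27 (0.47). CXCL1, a neutrophil chemokine, had 84 counts, and HSD11B1, which encodes the cortisol-regenerating enzyme that GA inhibits, had 7. At 12 h the con wells gave 0 IL6 counts of 1668402, which allows up to 1.8 CPM. The GA wells gave 0 of 2977023, which allows up to 1.01, so a change in IL6 was not detectable at this depth. Such limits cover counting error only. Other SASP genes had more counts. Over all wells the collagenase MMP1 had 423 CPM, the chemokine CCL2 376 and the chemokine CXCL8, interleukin 8, 33.7. CXCL8 was low in con at the late times, with 10 counts at 12 h (5.99 CPM) and 8 at 24 h (2.46), against 83.6 CPM at 4 h.

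GA was compared with con to see what the compound changed in senescent cells without added IL6. At 12 h and 24 h genes of amino acid synthesis and transport and of the tRNA synthetases rose, a set known to be controlled by the transcription factor ATF4 in the integrated stress response. ATF4 itself rose by 1.87 ± 0.17 (log2, SE, adjusted p = 5.7e-20) at 12 h and by 1.37 ± 0.15 (adjusted p = 3.49e-15) at 24 h. PSAT1, an enzyme of serine synthesis, stood at 16.3 ± 6.71 CPM (SD, n = 7, scaled by TMM library sizes as are all means over wells of tested genes) in con and 194 ± 31.9 (n = 8) in GA at 12 h. This was a log2 rise of 3.48 ± 0.27 (SE, adjusted p = 4.61e-27). At 24 h it stood at 18.5 ± 11.8 (SD, n = 8) and 148 ± 38.2 (n = 8), a rise of 2.92 ± 0.22 (SE, adjusted p = 2.25e-27). ASNS, the asparagine synthetase, rose by 3.17 ± 0.30 at 12 h (adjusted p = 1.52e-18) and by 3.11 ± 0.26 at 24 h (adjusted p = 4.9e-23). At each time all 8 GA wells lay above every con well for ATF4, PSAT1 and ASNS.

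Of the 28 tested genes of the ATF4 list, 23 rose at 12 h and 23 at 24 h, and 0 fell at either time. The median log2 changes were 1.62 and 1.44 (camera, adjusted p = 2.6e-71 and 2.58e-78). Adjusted over the list alone, 26 and 25 rose. MTHFD2, of mitochondrial folate metabolism, rose by 2.95 at 12 h and 1.79 at 24 h. The amino acid carrier subunit SLC3A2 rose by 2.12 and 1.85, and the pseudokinase gene TRIB3 by 3.42 and 2.97. DDIT4, an inhibitor of mTORC1, rose by 3.32 and 2.87, and PCK2, the mitochondrial PEP carboxykinase, by 3.39 and 2.14. Their adjusted p lay between 6.89e-29 and 0.000137.

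Genes of the endoplasmic reticulum rose with them. Of 21 tested chaperone and unfolded protein response genes, 5 rose at 12 h and 5 rose and 1, DNAJC3, fell at 24 h (6, 7 and 1 adjusted over the list alone). Median log2 changes were 0.35 and 0.25 (camera, adjusted p = 0.000121 and 5.17e-06). HSPA5, the chaperone BiP, rose by 1.04 ± 0.14 at 12 h (adjusted p = 1.82e-10) and 0.55 ± 0.13 at 24 h (adjusted p = 0.00408). HERPUD1, of ER-associated degradation, rose by 1.89 and 1.33, and the secreted factor MANF by 1.25 and 0.87. Without the low-count filter MANF (adjusted p = 0.0609) and DNAJC3 (0.0647) did not pass at 24 h.

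Sterol synthesis genes rose and a sterol exporter fell. Of 27 tested cholesterol and fatty acid synthesis genes, 7 rose at 12 h and 9 at 24 h and 0 fell (12 and 15 rose adjusted over the list alone). The list medians were 0.58 and 0.59 (camera, adjusted p = 1.83e-08 and 5.4e-15). The sterol demethylation enzyme MSMO1 rose by 1.03 and 1.49 ± 0.17 (adjusted p = 6.08e-13 at 24 h). Squalene synthase FDFT1 rose by 0.83 and 0.83, and the desaturase SCD by 0.76 and 0.76. ABCA1, which exports cholesterol and is a target of the nuclear receptor LXR, fell by 1.47 ± 0.41 at 12 h (adjusted p = 0.0163). At 24 h it fell from 92.8 ± 15.9 CPM in con (SD, n = 8) to 13.9 ± 8.57 in GA (n = 8), a log2 change of -2.60 ± 0.27 (SE, adjusted p = 3.1e-16), with all 8 GA wells below every con well. The LXR list held 6 tested genes at 24 h, of which ABCA1 fell and the lipid droplet gene PLIN2 rose. The list median was -0.33 (adjusted p = 0.034, and adjusted p = 0.0561 with an estimated correlation).

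Hypoxia and glycolysis genes rose at 24 h. Of 25 tested, 12 rose and 0 fell (21 rose adjusted over the list alone), with a median of 0.69 (camera, adjusted p = 1.47e-30). BNIP3, a mitophagy receptor, rose from 134 ± 17.7 to 358 ± 73.9 CPM (SD, n = 8 each), by 1.40 ± 0.14 (SE, adjusted p = 2.08e-17; all 8 GA wells above every con well). NDRG1 rose by 1.89, hexokinase HK2 by 1.71 and enolase ENO2 by 1.40. At 12 h 2 of the 25 rose (HK2 by 1.11, with adjusted p = 0.102 without the low-count filter, and the glucose transporter SLC2A3 by 1.25). The median was 0.26, and the list passed with the preset correlation (adjusted p = 0.0174, and adjusted p = 0.137 with an estimated correlation). The difference between the times was itself tested. The list's GA effect was higher at 24 h than at 12 h by a median of 0.47 (camera, adjusted p = 1.08e-11). That of the contractile list was higher by 0.31 (adjusted p = 1.51e-05).

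Glucocorticoid receptor targets rose as well, 2 of 10 at 12 h and 3 of 10 at 24 h (4 and 3 adjusted over the list alone). The medians were 0.52 and 0.32 (camera, adjusted p = 0.000487 and 0.00162). At 12 h these were the phosphatase DUSP1 (1.13) and the metallothionein MT1X, from 37.5 ± 9.26 CPM in con (SD, n = 7) to 76.8 ± 25.4 in GA (n = 8). At 24 h they were MT1X (1.34), the EGFR inhibitor ERRFI1 (1.44) and TSC22D3, also named GILZ (1.47). MT1X is near-identical to other metallothioneins, so its value is uncertain.

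SASP genes moved both ways. The urokinase receptor PLAUR rose by 1.01 at 12 h and GDF15 by 2.10. The growth factor FGF7 fell by 0.81 and 1.18 at 12 h and 24 h. The IGF binding protein IGFBP5 fell by 0.88 and 0.55, the last of these not with RLE scaling (adjusted p = 0.076) or in 4 other alternatives (adjusted p of 0.0609 to 0.108). Of the 30 tested SASP proteases, growth factors and matrix regulators 6 rose and 2 fell at 12 h (9 and 3 adjusted over the list alone; median 0.31, adjusted p = 0.0143, and adjusted p = 0.123 with an estimated correlation). TNFRSF11B, the decoy receptor osteoprotegerin, fell by 1.36 at 12 h and 0.72 at 24 h. It was the 1 gene of the 6 tested SASP cytokines and chemokines to pass at 24 h (3 fell adjusted over the list alone; list median -0.43, mean -0.14, camera adjusted p = 0.0181). CCL2 had a log2 change of -0.81 (adjusted p = 0.138) at 24 h and CXCL8 one of 1.95 (adjusted p = 0.113) at 12 h, neither past the threshold over all genes. With the pool fitted alone both passed (CCL2 -0.80, adjusted p = 0.0358, and CXCL8 1.93, adjusted p = 0.00897). MMP1, MMP3, IGFBP3, the cell cycle inhibitors CDKN1A and CDKN2A, STAT3 and the NF-kB inhibitor NFKBIA did not pass at 12 h or 24 h either, except NFKBIA at 12 h with the replicate block (0.95, adjusted p = 0.0216).

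Fibroblast, contractile and proliferation genes were lower. COL3A1, type III collagen, fell by 0.66 at 12 h (adjusted p = 0.014, and 0.0513 with RLE scaling) and by 1.03 at 24 h (adjusted p = 4.33e-07). Of 15 fibroblast identity markers 3 fell at 24 h, COL3A1, the protease FAP (-0.76) and the growth factor receptor PDGFRA (-0.55; adjusted p = 0.0668 with RLE scaling and 0.066 with DESeq2). In that list 5 fell adjusted over the list alone (median -0.24, camera adjusted p = 0.000121). At 12 h 1 of them fell (median -0.18, adjusted p = 0.0163, and adjusted p = 0.0787 with an estimated correlation, and 0.787 with all wells kept). Of 14 contractile genes 4 fell at 12 h, among them LMOD1 (-1.43) and the smooth muscle actin gene ACTA2 (-1.11), 5 adjusted over the list alone (median -0.25, camera adjusted p = 1.29e-05, and 0.437 with all 192 wells kept). Of 23 cell cycle genes 2 fell at 12 h, cyclin D1 (CCND1, -0.79) and the replication helicase subunit MCM4 (-1.35). At 24 h 3 fell, with the proliferation marker MKI67 (-1.03) among them (3 at 12 h and 10 at 24 h adjusted over the list alone). That list's medians were -0.44 and -0.58 (adjusted p = 0.000729 and 7.89e-07, and adjusted p = 0.208 and 0.0705 with an estimated correlation).

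Interferon-stimulated genes were lower in GA than in con at 12 h, 4 of 10 over all genes and 7 adjusted over the list alone, with a median of -0.73 (camera, adjusted p = 2.84e-05). The log2 change was -2.83 in IFIT1, -1.78 in IFI6 and -1.21 in the ubiquitin-like modifier ISG15. All 8 GA wells lay below the con mean for each of them. Below every con well lay 0 of 8 for IFIT1, 7 for IFI6 and 5 for ISG15. IFI6 was also lower in the IL6 wells than in con at 12 h (-1.64, adjusted p = 2.12e-05) and did not differ past the threshold between IL6andGA and IL6 (0.07, adjusted p = 0.953). Its mean was 108 ± 43.6 CPM in con (SD, n = 7), 30.6 ± 7.53 in GA, 34.1 ± 13.1 in IL6 and 34.7 ± 7.34 in IL6andGA (n = 8 each). At 24 h 0 of the 10 passed (edgeR, and 0 adjusted over the list alone; median -0.29, adjusted p = 0.0417, and adjusted p = 0.0741 with an estimated correlation).

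In all, edgeR's quasi-likelihood test found 360 genes past an adjusted p of 0.05 at 12 h, 203 higher and 157 lower in GA, and 232 at 24 h, 143 higher and 89 lower. The 2 times shared 73 of the higher and 25 of the lower genes, where independent lists of these sizes would share 3.67 and 1.77 (the wells of both times were in 1 pool), and RMRP fell at 12 h (-1.79) and rose at 24 h (0.81, adjusted p = 0.049, and 0.0681 to 0.127 in 4 alternatives). Besides the lists named above, the NF-kB (adjusted p = 0.0575 with an estimated correlation), immediate early (0.0612), oxidative phosphorylation (0.511) and nuclear RNA (0.123) lists at 12 h and the YAP (0.24) and ribosomal protein (0.509) lists at 24 h passed with the preset correlation alone. The TGF-beta list at 12 h (2 of 17 rose, among them the matricellular gene CTGF, which had adjusted p = 0.0691 with the replicate block and 0.0522 with the length slope as a covariate, and 1 fell; median 0.37, adjusted p = 0.00445) and the senescence marker list at 24 h (1 of 10 fell; median -0.24, adjusted p = 0.0181) passed with both. With each pool fitted alone the counts were 565 and 405. The genes quoted most lie, in GENCODE release 29 on GRCh38, at chromosome 9, 78297143 to 78330093 (PSAT1), chromosome 7, 97852118 to 97872542 (ASNS), chromosome 9, 104781002 to 104928237 (ABCA1), chromosome 2, 188974320 to 189012746 (COL3A1) and chromosome 10, 131966455 to 131982013 (BNIP3), all protein-coding.

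**Figure D2:**
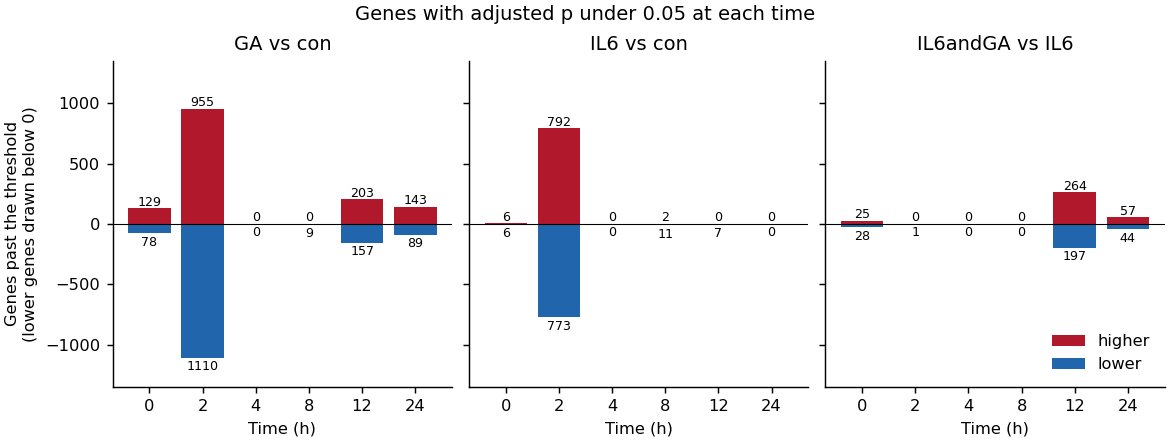
Number of genes past an adjusted p of 0.05 at each time in h, higher genes above and lower genes below 0, for GA vs con, IL6 vs con and IL6andGA vs IL6. GA vs con and IL6 vs con reach 2065 and 1565 genes at 2 h, and both GA comparisons have 101 or more at 12 h and 24 h.

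At 4 h and 8 h few genes passed. At 4 h 0 genes passed by edgeR (405 at an unadjusted p under 0.05, and 0 by DESeq2). The contractile, hypoxia and SASP protease lists were lower at 4 h with the preset correlation (adjusted p = 0.0494 each, and adjusted p = 0.384, 0.386 and 0.384 with an estimated correlation). At 8 h 9 genes were lower in GA, among them the cation channel TRPA1 (-1.65), the calcium-binding NUCB2 (-1.46) and C5orf24 (-3.82), with 5 GA wells. With RLE scaling these 3 did not pass (adjusted p = 0.119, 0.0566 and 0.0566). TRPA1 also did not pass with the replicate block (0.0686), NUCB2 with DESeq2 (0.0626) or C5orf24 without GA 8 h replicate 2 (0.0502), 6 (0.0557) or 7 (0.0531). RLE gave 1 gene higher and 0 lower, and with DESeq2 22 were higher and 1 lower. In simulated counts of these depths 15.9% of the genes called at 8 h were unchanged ones. RLE moved the median of all genes at 8 h from a log2 change of -0.27 to -0.01. By edgeR there were 25, 4 and 26 genes without GA 8 h replicates 4, 6 and 7 and 107 (2 higher, 105 lower) with each well's length slope as a covariate.

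At 2 h 2065 genes differed between GA and con, 955 higher and 1110 lower, and ribosomal protein genes lay lower. Of 56 ribosomal protein genes 34 fell (36 adjusted over the list alone; median -0.58), RPL7 by 1.12. Of 25 hypoxia and glycolysis genes 8 fell (8 adjusted over the list alone), the lactate dehydrogenase LDHA by 0.91. Ribosomal protein genes have near-identical pseudogenes, so their single values are uncertain. These lists and the oxidative phosphorylation list (13 of 36 lower, 1 higher, and 13 and 1 adjusted over the list alone) passed with the preset correlation (adjusted p = 3.91e-20, 0.0115 and 0.0368). They had adjusted p = 0.607, 0.607 and 0.646 with an estimated correlation. RNF169, a reader of ubiquitinated chromatin, was higher by 3.51 (5 of 8 GA wells above the con mean) and APAF1, of the apoptosome, by 2.89 (4 of 8). MAMDC2 changed by -2.32, with all 8 GA wells below every con well. The con wells of 2 h had the lowest mean slope on transcript length of any group, at -0.178 ± 0.076 (SD, n = 8) log2 per doubling. The GA wells of 2 h had 0.063 ± 0.097 (n = 8). Single wells of other groups overlapped those of con, such as GA 0 h replicate 8 at -0.2738 and IL6andGA 0 h replicate 1 at -0.1924. With each well's slope as a covariate 611 genes passed (347 higher, 264 lower), without RNF169 (adjusted p = 0.0749) and APAF1 (0.334). RLE scaling gave 1487 higher and 660 lower and DESeq2 1638 and 679, and RLE moved the median of all genes from 0.02 to 0.21.

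At 0 h 207 genes differed between the GA and con wells, 129 higher and 78 lower. The neurochondrin gene NCDN stood higher by 1.77 ± 0.23 (adjusted p = 3.01e-09) and RNF44 by 1.60, and ANKRD44 had a log2 change of -1.88. The hypoxia and ribosomal protein lists were higher (medians 0.18 and 0.14, adjusted p = 0.0279 and 3.59e-06, and adjusted p = 0.523 and 0.895 with an estimated correlation). The ATF4 list had a median of 0.23. With the pool fitted alone 42 genes passed, with the length slope as a covariate 60 did (45 higher, 15 lower, without ANKRD44, adjusted p = 0.151), and RLE scaling gave 88 higher and 121 lower.

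Averaged over 2 to 24 h, 251 genes passed, 70 higher and 181 lower in GA. ALDH1L2, of mitochondrial folate metabolism, rose by 0.85 ± 0.19 (SE, adjusted p = 0.00233), with the same sign at all 5 times. The urea transporter SLC14A1 fell by 1.74, the matricellular gene NOV by 0.99, the kinesin KIF20A by 0.99 and TNFRSF11B by 0.72. MMP1 fell by 0.51 (adjusted p = 0.00151), and without the 2 h wells by 0.34 (adjusted p = 0.129). Of the ATF4 list 12 of 28 rose (15 adjusted over the list alone; median 0.53, adjusted p = 1.13e-34). The chaperone list (2 of 21 rose and 1 fell, 4 and 1 adjusted over the list alone; median 0.08, adjusted p = 0.000122) and the nuclear RNA list (1 of 6, MEG3, with adjusted p = 0.0633 without the 2 h wells and 0.0529 without the 2 h and 8 h wells, 3 adjusted over the list alone; median 0.15, adjusted p = 0.0011) rose. The 7 other lists past the preset correlation had adjusted p of 0.0536 to 0.3 with an estimated correlation. In simulated counts 11.5% of the genes called over the mean were unchanged ones. The share of higher genes turned with the scaling (RLE 162 higher and 40 lower, DESeq2 222 and 46). By edgeR 731 genes passed without the 8 h wells and 157 without GA 8 h replicate 5.

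IL6 was compared with con to see what the cytokine did alone in senescent cells. Over 2 to 24 h 0 genes passed by edgeR (864 at an unadjusted p under 0.05, and 73 by DESeq2, 64 higher and 9 lower; 37 with RLE scaling). The IL6-JAK-STAT3 list of 14 tested genes did not pass at any time, with medians of 0.34 at 2 h, -0.16 at 4 h, 0.16 at 12 h and 0.04 at 24 h (adjusted p = 0.131, 0.109, 0.132 and 0.996). SOCS3, the feedback inhibitor of the IL6 receptor, was under the count filter and stood at 7.49 ± 6.91 CPM in IL6 and 6.86 ± 3.51 in con at 24 h (SD, n = 8 each, scaled by well totals; exact permutation test, two-sided p = 0.837, adjusted p = 1 over 36 tests of SOCS3 and CXCL1). Among the SASP and growth arrest genes named beforehand CCL2 (-0.10), MMP1 (-0.31), CDKN1A (0.11) and STAT3 (-0.06) had adjusted p between 0.193 and 0.885. Lists that passed over the mean with the preset correlation were cell cycle (-0.20), hypoxia (-0.09), oxidative phosphorylation (-0.11) and ribosomal proteins (-0.10), all lower, and immediate early genes (0.09), higher. These had adjusted p of 0.404 to 0.551 with an estimated correlation.

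At single times IL6 and con differed in 12 genes at 0 h, 1565 at 2 h, 0 at 4 h, 13 at 8 h, 7 at 12 h and 0 at 24 h (edgeR; 281 at 4 h and 206 at 24 h at an unadjusted p under 0.05, and 0 at both by DESeq2). At 12 h IFI6 (-1.64), the RNase MRP RNA gene RMRP (-1.56) and MTRNR2L2, a nuclear copy of mitochondrial rRNA that can share its reads, (-1.38) were lower, the same con wells being the reference as for GA. At 8 h the proteoglycan GPC1 (1.15) was higher (adjusted p = 0.0592 with the replicate block, which left 0 genes higher, and 0.0648 without the low-count filter). The mitotic PRC1 (-1.98) and the nucleosome-binding HMGN2 (-1.37) fell, 2 higher and 11 lower in all (RLE 10 and 5, DESeq2 19 and 11, with the median of all genes moved by RLE from -0.12 to 0.01). At 0 h IFI6 (1.73) and the antiviral IFITM1 (1.21) were higher, among 6 higher and 6 lower (RLE 4 and 12, DESeq2 11 and 30). At 2 h 792 genes were higher and 773 lower (RLE 1227 and 362, DESeq2 1338 and 390), with 39 of 56 ribosomal protein genes lower (49 adjusted over the list alone). The length slope was 0.020 ± 0.068 (SD, n = 8) in the IL6 wells and -0.178 ± 0.076 (n = 8) in con. With the slope as a covariate 150 genes passed, while RLE moved the median of all genes from 0.03 to 0.19. The lists that passed at single times with the preset correlation, 5 at 0 h, 3 at 2 h, 2 at 4 h, 4 at 8 h, 4 at 12 h and 3 at 24 h, had adjusted p of 0.0505 or more with an estimated correlation.

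IL6andGA was compared with IL6 to see GA's effect in the presence of the cytokine. At 12 h amino acid synthesis genes rose. PSAT1 went from 16.2 ± 11.2 to 248 ± 71.2 CPM (SD, n = 8 each), by 3.85 ± 0.25 (SE, adjusted p = 6.15e-36). ASNS rose by 3.53, ATF4 by 2.08 and TRIB3 by 3.97. Of the 28 ATF4 list genes 26 rose at 12 h and 8 at 24 h (26 and 11 adjusted over the list alone). The medians were 2.09 and 0.52 (camera, adjusted p = 9.18e-90 and 2.11e-15). At 24 h PSAT1 rose by 1.77 ± 0.25 (SE, adjusted p = 2.24e-08) and ASNS by 1.71, while TRIB3 (0.03, adjusted p = 0.992) and DDIT4 (0.52, adjusted p = 0.816) did not pass. All 8 IL6andGA wells lay above every IL6 well at both times for PSAT1 and ASNS.

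Matrix and fibroblast genes fell at 12 h in the presence of IL6. COL3A1 fell from 402 ± 43.8 to 82.3 ± 32.5 CPM (SD, n = 8 each), a log2 change of -2.28 ± 0.21 (SE, adjusted p = 1.08e-19), and COL1A1, type I collagen, by 1.33. Of 15 fibroblast identity markers 6 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.46, adjusted p = 4.3e-08), PDGFRA by 1.10. Of 27 collagen and fibrillar matrix genes 5 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.23, adjusted p = 2.17e-05, and adjusted p = 0.0705 with an estimated correlation). At 24 h 2 of the 15 markers fell (5 adjusted over the list alone; median -0.28, adjusted p = 1.65e-05). Replication genes fell at 12 h, the polymerase clamp PCNA by 1.62 and MCM4 by 1.62, among 4 lower and 1 higher of 23 cell cycle genes (5 and 1 adjusted over the list alone; median -0.57, adjusted p = 0.000136, and adjusted p = 0.151 with an estimated correlation). The higher gene was CCND1, which did not pass without the low-count filter (adjusted p = 0.0752), with all wells kept (0.0593) or with wells at 50% of the pool median or more (0.144).

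Secreted factors and receptor targets changed with them at 12 h. CXCL8 rose by 3.10 ± 0.61 (SE, adjusted p = 8.61e-05; all 8 IL6andGA wells above every IL6 well), the vascular growth factor VEGFA by 2.86 and the stress cytokine GDF15 by 2.92, while FGF7 fell by 1.66 and TNFRSF11B by 1.27. Of 30 SASP proteases, growth factors and matrix regulators 7 rose and 1 fell at 12 h (13 and 2 adjusted over the list alone; median 0.42, adjusted p = 0.000488, and adjusted p = 0.0491 with an estimated correlation). At 24 h 5 rose, the protease nexin SERPINE2 by 1.10 and the plasminogen activator PLAT by 1.24, and 1 fell (9 and 4 adjusted over the list alone; median 0.04, adjusted p = 0.00471, and adjusted p = 0.0822 with an estimated correlation). Of 10 glucocorticoid receptor targets 5 rose at 12 h (6 adjusted over the list alone; median 0.64, adjusted p = 0.000243), ERRFI1 by 2.05 and TSC22D3 by 2.52.

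At 24 h hypoxia, chaperone and sterol genes rose and antioxidant and lysosome genes fell. Of 25 hypoxia and glycolysis genes 7 rose (12 adjusted over the list alone; median 0.37, adjusted p = 2.11e-15), the pyruvate dehydrogenase kinase PDK1 by 1.75, LDHA by 0.68 and BNIP3 from 133 ± 25.4 to 267 ± 45.0 CPM (SD, n = 8 each). The chaperone HSP90B1 rose by 0.54, and 2 of its list of 21 passed (10 adjusted over the list alone; median 0.37, adjusted p = 2.32e-06). MSMO1 rose by 0.80 and the demethylase CYP51A1 by 0.71, among 3 of 27 synthesis genes (7 adjusted over the list alone; median 0.27, adjusted p = 5.65e-06). ABCA1 fell by 1.51 (adjusted p = 1.19e-07). Of 18 NRF2 targets 4 fell (6 adjusted over the list alone; median -0.32, adjusted p = 1.65e-05), the quinone reductase NQO1 by 0.63 and the ferritin chains FTL by 0.66 and FTH1 by 0.60. Both ferritin genes have processed pseudogenes that can share their reads and did not pass with all wells kept (adjusted p = 0.113 and 0.0925). Of 24 lysosome and autophagy genes 4 fell (5 fell and 1 rose adjusted over the list alone; median -0.22, adjusted p = 8.14e-05), the autophagy receptor SQSTM1 by 0.79 and cathepsin D (CTSD) by 0.74 (adjusted p = 0.0934 with the length slope as a covariate). The 10 interferon-stimulated genes lay lower as a set (median -0.31, adjusted p = 0.00566), with 0 passing singly by edgeR (0 adjusted over the list alone).

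By edgeR 461 genes passed at 12 h, 264 higher and 197 lower, and 101 at 24 h, 57 higher and 44 lower (231 with the pool fitted alone). At 2 h 1 gene passed, CCND1 (-0.62, adjusted p = 0.046), which did not pass in 5 of the alternatives (adjusted p of 0.0556 to 0.539). At 4 h and 8 h 0 passed (edgeR; 356 and 517 at an unadjusted p under 0.05, and 0 at both by DESeq2; 1 at 8 h without IL6andGA 8 h replicate 5). At 0 h 53 genes differed, 25 higher and 28 lower (DESeq2 52 and 116), with CCL2 higher by 1.31 (adjusted p = 0.00485). With the length slope as a covariate 3 did, without CCL2 (adjusted p = 0.134). Over 2 to 24 h 98 genes passed, 73 higher and 25 lower. Log2 changes were 1.51 in PSAT1, 0.68 in the growth factor FGF2, -1.01 in the integrin ITGB8 and -0.58 in the Wnt inhibitor DKK1, and 312 passed without the 8 h wells. Over that mean the ATF4 (median 0.47, adjusted p = 3.71e-28), interferon (-0.17, 0.00584) and fibroblast marker (-0.18, 2.04e-05) lists passed with both correlations, the interferon list not with all wells kept (adjusted p = 0.0587). Lists that passed with the preset correlation alone, 10 over the mean, 2 at 0 h, 6 at 2 h, 7 at 4 h, 9 at 12 h and 4 at 24 h, had adjusted p of 0.0526 or more with an estimated correlation.

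**Figure D3:**
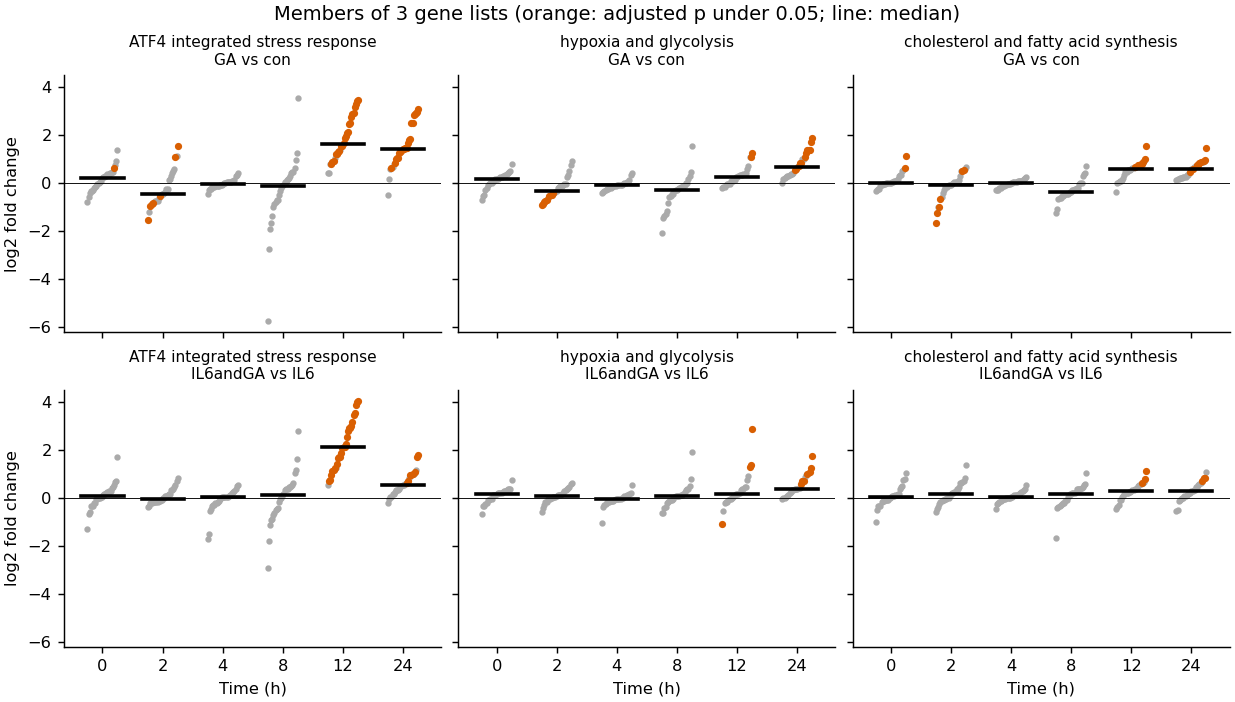
Log2 fold change of each tested member of 3 gene lists (points, orange where the adjusted p was under 0.05) with the list's median (line), at each time in h, for GA vs con and IL6andGA vs IL6. The ATF4 list medians lie at 1.62 and 1.44 at 12 h and 24 h without IL6 and at 2.09 and 0.52 with it.

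**Figure D4:**
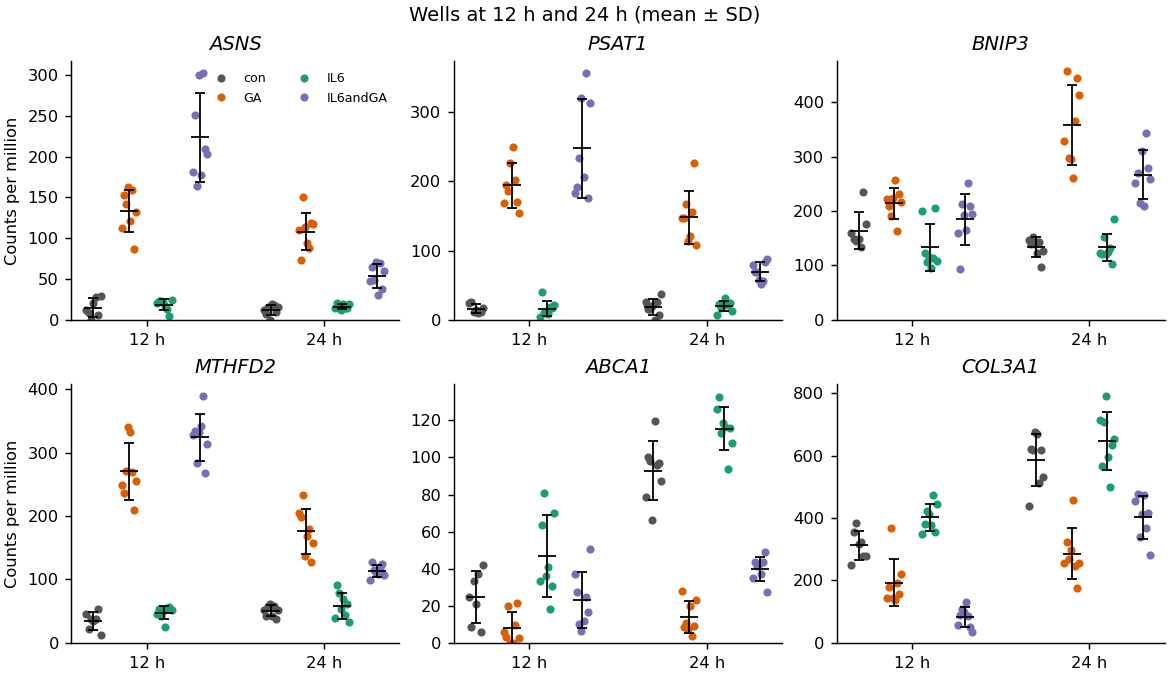
CPM in each well at 12 h and 24 h (points, with mean and SD) for 6 genes in the 4 treatments, 7 wells in con at 12 h and 8 in each other group. ASNS, PSAT1 and MTHFD2 lie higher and ABCA1 and COL3A1 lower in both arms with GA.

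Genes changed by GA were then compared between the arms without and with IL6. At 12 h 103 genes rose and 40 fell in both arms, where independent lists of these sizes would share 6.78 and 3.91. At 24 h 32 rose and 6 fell in both, against 1.03 and 0.496. Some genes moved in opposite directions. At 12 h 6 genes, CCND1 among them, fell without IL6 and rose with it, and at 24 h the clathrin light chain CLTA (0.52 without IL6 and -0.61 with it) and PRKCDBP (0.97 and -1.23) rose without it and fell with it. Without the low-count filter the rises of CLTA (adjusted p = 0.0621) and PRKCDBP (0.0538) did not pass, nor did the fall of CLTA with the length slope as a covariate (0.0845). The arms share no wells. Among the 18 genes that rose in both arms at both times were AARS, EPRS, GARS, MARS, SARS, TARS and YARS, which are tRNA synthetases, ASNS, PSAT1, MTHFD2, ALDH1L2, ATF4, the arginine carrier SLC7A1, MSMO1, the claudin CLDN1, FMN1 and UAP1. The 3 that fell in both arms at both times were ABCA1, COL3A1 and the myosin kinase MYLK. These calls did not all hold in the alternatives. With IL6 at 12 h ABCA1 had adjusted p = 0.0657 with the replicate block, 0.0689 with RLE scaling and 0.0512 without the robust option, and at 24 h ATF4 had adjusted p = 0.0608 without the low-count filter. Without IL6 at 12 h COL3A1 had adjusted p = 0.0513 with RLE scaling. Across the 7901 genes, which are not independent replicates, the edgeR GA effects in the 2 arms had a Pearson correlation of 0.403 at 12 h (Spearman 0.272) and 0.192 at 24 h (0.131). Computed from mean log2 CPM the Pearson correlations were 0.386 and 0.194. In that measure 100 permutations of the well labels gave -0.179 to 0.167 and -0.133 to 0.158. At 0 h the edgeR correlation was 0.374. From log2 CPM it was 0.337, at the top of the permuted range of -0.429 to 0.337.

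The size of the ATF4 response differed between the arms at 24 h. The GA effect on the list was lower with IL6 than without by a median log2 difference of -0.86, with 25 of 28 members lower (camera, adjusted p = 1.23e-21, and adjusted p = 1.72e-11 with an estimated correlation). With the preset correlation alone the effect was also lower on ribosomal protein (-0.26), hypoxia (-0.32), cholesterol (-0.31) and oxidative phosphorylation (-0.12) genes and higher on cell cycle genes (0.42), with adjusted p of 0.151 to 0.857 with an estimated correlation. At 12 h the effect on the ATF4 list was higher with IL6 by 0.31 (adjusted p = 0.00664, and adjusted p = 0.0654 with an estimated correlation), and that on the fibroblast markers was lower (median difference -0.40, adjusted p = 0.00664, and adjusted p = 0.0654 with an estimated correlation). Collagen (-0.08), contractile (0.32), oxidative phosphorylation (0.09) and ribosomal protein (0.08) genes passed at 12 h with the preset correlation alone (adjusted p of 0.374 to 0.869 with an estimated correlation). These tests at 12 h and 24 h were chosen after the data were seen. In the interaction over 2 to 24 h 23 genes passed, 21 higher and 2 lower, with differences of 1.08 in the calcineurin regulator RCAN1, 1.11 in DENND5A and -0.39 in the cytoplasmic actin ACTG1, whose pseudogenes can share its reads. Here 0 of the 27 lists passed by camera. Without the 2 h and 8 h wells RCAN1 (0.17, adjusted p = 0.825), DENND5A (0.49, adjusted p = 0.306) and ACTG1 (-0.30, adjusted p = 0.268) did not pass. DENND5A did not pass without GA 8 h replicate 5 (adjusted p = 0.0662), with RLE scaling (0.0804) or with all wells kept (0.108), nor ACTG1 without GA 8 h replicate 7 (0.0595). RLE scaling gave 4 higher and 6 lower and DESeq2 13 and 27.

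Con wells were also compared between the times of each pool, to describe change without treatment. From 12 h to 24 h 146 genes changed, 75 rising and 71 falling (RLE 128 and 53, DESeq2 155 and 75). The BMP and TGF-beta targets ID3 (-3.09 ± 0.28, adjusted p = 2.69e-17) and ID1 (-2.26) fell. Of 17 TGF-beta and SMAD targets 4 fell (4 fell and 1 rose adjusted over the list alone; median -0.31, adjusted p = 5.56e-07). Of 14 contractile genes 3 fell (8 adjusted over the list alone; median -0.37, adjusted p = 2.54e-09), and 1 of 14 IL6-JAK-STAT3 genes, the receptor LIFR, rose (4 adjusted over the list alone; median 0.36, adjusted p = 0.000479). From 4 h to 8 h 36 genes changed, 18 each way (DESeq2 45 rising and 27 falling), with log2 changes of -2.10 in CXCL8 and 1.14 in the inositol carrier SLC5A3. The NF-kB list fell (1 of 13 genes, NFKBIA, and 5 adjusted over the list alone; median -0.65, adjusted p = 8.66e-06), and the heat shock list rose (1 of 15, DNAJA1, and 3 adjusted over the list alone; median 0.13, adjusted p = 0.0126). With wells at 50% of the pool median or more NFKBIA (adjusted p = 0.103) and DNAJA1 (0.0566) did not pass, nor did DNAJA1 without the low-count filter (0.202). From 0 h to 2 h 3161 genes differed (1493 higher and 1668 lower; RLE 865 and 2450, DESeq2 898 and 2492), with sphingosine kinase SPHK1 higher by 2.14 and stanniocalcin STC1 by 2.05, and 109 passed with the length slope as a covariate. RLE moved the median of all genes there from -0.07 to -0.28. Ribosomal protein genes were higher at 2 h, 42 of 56 (44 adjusted over the list alone), with an adjusted p = 1.69e-22, and adjusted p = 0.293 with an estimated correlation.

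The GA effect itself differed between the times of a pool in 2486 genes from 0 h to 2 h (1215 higher and 1271 lower; RLE 1807 and 822, DESeq2 1923 and 856; 672 with the length slope as a covariate; median moved by RLE from 0.06 to 0.31), in 11 from 4 h to 8 h and in 10 from 12 h to 24 h. Those of 12 h to 24 h were all higher, RMRP by 2.60, IFI6 by 2.09, MTRNR2L2 by 1.91 and BNIP3 by 1.02 (adjusted p = 0.00362) among them. RMRP, IFI6 and MTRNR2L2 also differed between IL6 and con at 12 h. RLE scaling gave 7 higher and 1 lower there and DESeq2 19 and 8. Those of 4 h to 8 h were all lower, with a difference of -1.54 in the splicing factor SFPQ (adjusted p = 0.074 with RLE scaling). They turned to 1 higher and 0 lower with RLE (median moved from -0.29 to -0.05) and 17 and 4 with DESeq2, and to 7 and 1 in all without GA 8 h replicates 6 and 7. Markers of other cell types gave no comparison. Of these, 1 of 16 epithelial, 0 of 12 endothelial, 1 of 18 blood and immune and 3 of 13 mural and mesothelial markers were tested.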

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

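The length slope as a covariate, the ATF4 list at 0 h and the difference between the arms at 24 h alone were tests chosen only after the result was seen.

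The GA effect was tested for differences between arms and times. In the interaction of GA and IL6 over 2 to 24 h 23 genes passed, with RCAN1 and DENND5A among those higher. The GA effect differed in 2486 genes between 0 h and 2 h, in 11 between 4 h and 8 h and in 10 between 12 h and 24 h, BNIP3 and IFI6 among the last. Between 12 h and 24 h the effect on hypoxia and glycolysis genes was higher by a median of 0.465 and that on contractile genes by 0.313. With IL6 the effect on the ATF4 list at 24 h was lower than without it by a median of -0.857.

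Of 144 tests for a single well that stood far from the others of its group, over 24 groups and 6 measures, 10 found such a well, where chance gives about 1 in 20. The total of IL6andGA 12 h replicate 1 was 508887 counts against 130263 to 272232 in the others. The mean log2 CPM of the ATF4 list in GA 24 h replicate 8 was 5.979, against 6.162 to 6.289. For hypoxia and glycolysis genes it was 7.079 in con 0 h replicate 8 (6.75 to 6.856 in the others), 6.719 in con 2 h replicate 4 (6.872 to 7.008) and 6.864 in GA 4 h replicate 4 (6.67 to 6.728). For cholesterol and fatty acid synthesis genes it was 5.967 in con 4 h replicate 4 (6.186 to 6.33), 6.345 in GA 4 h replicate 3 (6.123 to 6.215) and 5.138 in IL6 2 h replicate 8 (5.576 to 5.908). The IL6-JAK-STAT3 list stood at 5.807 in IL6 24 h replicate 4 (5.461 to 5.606), and the SASP cytokines and chemokines at 5.674 in IL6andGA 0 h replicate 1 (6.218 to 6.635).

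Random splits of the wells, 39 beside the real split for each gene count, were compared with it. For GA vs con only the real split gave as many genes (1 of 40) over the mean (251, highest other 1), at 0 h (207, 89), 2 h (2065, 1146), 8 h (9, 2), 12 h (360, 5) and 24 h (232, 1). The same held for IL6andGA vs IL6 over the mean (98, 0), at 0 h (53, 12), 12 h (461, 146) and 24 h (101, 1), for the interaction (23, 1) and for the GA effect from 0 h to 2 h (2486, 274), 4 h to 8 h (11, 2) and 12 h to 24 h (10, 1). It held too for IL6 vs con at 0 h (12, 0), 2 h (1565, 738) and 12 h (7, 0) and for con from 0 h to 2 h (3161, 333), 4 h to 8 h (36, 0) and 12 h to 24 h (146, 6). Chance was not excluded for IL6 vs con at 8 h, where 2 of 40 splits gave as many (13, highest other 30), nor for IL6andGA vs IL6 at 2 h, where 16 did (1, highest other 361), a split with many times the real count. The 2 h wells may thus hold a structure, whose source was not tested. All 40 splits gave as many where the real count was 0, as any split must, so these cannot decide on chance. They were IL6 vs con over the mean (highest other 1) and at 4 h and 24 h (0). The others were GA vs con at 4 h (0) and IL6andGA vs IL6 at 4 h (0) and 8 h (2).

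At 2 h the con wells differed from GA, IL6 and IL6andGA in 2065, 1565 and 2814 genes, and ribosomal protein genes lay lower in GA and IL6 than in con with the preset correlation alone (adjusted p = 0.607 and 0.317 with an estimated correlation). Lower depth of the treated wells is argued against by IL6andGA, whose median total of 401738 lay above the 363530 of con while 2814 genes differed. For a response of the treated wells to what was added, changes from 0 h to 2 h were counted in each arm. These were 1335 genes in GA, 99 in IL6, 1087 in IL6andGA and 3161 in con. Such counts also depend on the depth and spread of the wells, and a treatment that prevented a change in con would give the same. They thus cannot decide whether what was added was the main source. A difference between wells along transcript length stays open as a candidate cause: with each well's slope as a covariate the 2065 genes fell to 611. The slope was computed from the same counts, and its mean differed between con and GA. The covariate can thus also take out a response that runs along length, so this fall cannot decide. A response of the con wells to handling between 0 h and 2 h was not tested.

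ATF4 list genes were higher after GA at 12 h and 24 h in both arms, and the explanations were tested in GA vs con alone, not in the arm with IL6. A difference along transcript length is argued against, since the list's median at 24 h was 1.44 without and 1.427 with the slope as a covariate. For a difference in depth every well of that pool was thinned to 130263 counts, and the median at 12 h was then 1.464, over the 18 genes then tested. Thinning keeps each gene's expected share of a well's counts, so it cannot decide on a depth effect that arose before counting. Median totals of GA and con were 362952 and 232929 at 12 h and 334921 and 392297 at 24 h, while the list rose at both. A difference between the arms already as large at 0 h is argued against by the median of 0.231 there. Even so 207 genes differed between GA and con at 0 h (42 with the pool fitted alone) and 53 between IL6andGA and IL6 (3 with the pool fitted alone). Between IL6andGA and con 1370 differed and between GA and IL6 606, and the labels do not say whether the 0 h wells had received the compounds. A response of the cells to GA without IL6 through ATF4 is therefore a hypothesis that these data leave open, and a toxic effect of the 50 µM dose was not tested.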

How the results depend on the processing

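The values with each well's length slope as a covariate and the means without 2 h or 8 h were chosen after seeing the data, and the other alternatives before.

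Depth limited the 8 h comparisons most, where the GA wells kept held a median of 29233 counts and 22.2% of simulated 2-fold changes were recovered. The replicate block could not be fitted to the changes of con between times, since it lies within a file and time, each file alone gave no value for means over files, and at 50% of the pool median no GA, IL6 or IL6andGA wells were left at 8 h. The alternatives meant for wells without a known treatment were not run, as all columns gave one. No named gene reversed its direction past the threshold in any alternative, and ATF4, PSAT1 and ASNS kept their calls in GA vs con at 12 h and 24 h under each alternative run. Of the counts, IL6 vs con at 4 h, IL6andGA vs IL6 at 12 h and the lists of IL6andGA vs IL6 at 24 h stayed within 1.5 times under each alternative run.

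Apart from the ranges with single wells left out, each value given here lay beyond 1.5 times the reported one, and the cause was not tested except where fewer wells or genes made it. RLE scaling gave gene counts of 1 in GA vs con 8 h, 37 in IL6 vs con (mean), 10 in the interaction, 1 in GA effect 8 minus 4 h, and lists past the threshold numbered 1 in GA vs con 8 h, IL6 vs con (mean). The DESeq2 test gave gene counts of 23 in GA vs con 8 h, 73 in IL6 vs con (mean), 41 in IL6 vs con 0 h, 30 in IL6 vs con 8 h, 13 in IL6 vs con 12 h, 168 in IL6andGA vs IL6 0 h, 2 in IL6andGA vs IL6 2 h, 40 in the interaction, 72 in con 8 vs 4 h, 21 in GA effect 8 minus 4 h, 230 in con 24 vs 12 h, 27 in GA effect 24 minus 12 h. No low-count filter gave gene counts of 121 in GA vs con 0 h, 9 in IL6 vs con (mean), 0 in IL6andGA vs IL6 2 h, 1 in IL6andGA vs IL6 4 h, 1 in IL6andGA vs IL6 8 h, 7 in GA effect 8 minus 4 h. Estimation without the robust option gave gene counts of 16 in GA vs con 8 h, 6 in IL6 vs con (mean). Keeping all wells gave gene counts of 98 in GA vs con 8 h, 0 in IL6andGA vs IL6 2 h, 39 in GA effect 8 minus 4 h, and lists past the threshold numbered 0 in GA vs con 0 h, GA vs con 4 h, 1 in GA vs con 2 h, IL6 vs con (mean), IL6 vs con 4 h, IL6 vs con 24 h, IL6andGA vs IL6 4 h, 2 in GA vs con 8 h, 7 in the interaction, 10 in IL6andGA vs IL6 8 h. Keeping wells at 50% of the pool median or more gave gene counts of 26 in IL6 vs con 0 h, 11 in IL6 vs con 12 h, 95 in IL6andGA vs IL6 0 h, 0 in IL6andGA vs IL6 2 h, 20 in con 8 vs 4 h. Fitting each file alone gave gene counts of 42 in GA vs con 0 h, 3 in GA vs con 4 h, 17 in GA vs con 8 h, 565 in GA vs con 12 h, 405 in GA vs con 24 h, 2 in IL6 vs con 0 h, 19 in IL6 vs con 12 h, 1 in IL6 vs con 24 h, 3 in IL6andGA vs IL6 0 h, 0 in IL6andGA vs IL6 2 h, 1 in IL6andGA vs IL6 8 h, 231 in IL6andGA vs IL6 24 h, 93 in con 8 vs 4 h, 18 in GA effect 8 minus 4 h, 520 in con 24 vs 12 h, 45 in GA effect 24 minus 12 h. The replicate block gave gene counts of 5 in IL6 vs con (mean), 0 in IL6andGA vs IL6 2 h, 3 in GA effect 8 minus 4 h. A mean without 2 h gave gene counts of 166 in GA vs con (mean), 6 in IL6 vs con (mean). A mean without 8 h gave gene counts of 731 in GA vs con (mean), 65 in IL6 vs con (mean), 312 in IL6andGA vs IL6 (mean), 55 in the interaction. A mean without 2 h and 8 h gave gene counts of 4 in IL6 vs con (mean), 390 in IL6andGA vs IL6 (mean). The length slope as a covariate gave gene counts of 60 in GA vs con 0 h, 611 in GA vs con 2 h, 3 in GA vs con 4 h, 107 in GA vs con 8 h, 13 in IL6 vs con (mean), 47 in IL6 vs con 0 h, 150 in IL6 vs con 2 h, 63 in IL6 vs con 8 h, 12 in IL6 vs con 12 h, 3 in IL6andGA vs IL6 0 h, 5 in IL6andGA vs IL6 2 h, 40 in the interaction, 109 in con 2 vs 0 h, 672 in GA effect 2 minus 0 h, 86 in con 8 vs 4 h, 74 in GA effect 8 minus 4 h, 39 in GA effect 24 minus 12 h. An estimated correlation left lists past the threshold numbering 0 in GA vs con 0 h, GA vs con 2 h, GA vs con 4 h, IL6 vs con (mean), IL6 vs con 0 h, IL6 vs con 2 h, IL6 vs con 4 h, IL6 vs con 8 h, IL6 vs con 12 h, IL6 vs con 24 h, IL6andGA vs IL6 0 h, IL6andGA vs IL6 2 h, IL6andGA vs IL6 4 h, 3 in GA vs con (mean), IL6andGA vs IL6 (mean), 4 in IL6andGA vs IL6 12 h, 7 in GA vs con 12 h, 8 in GA vs con 24 h. For changes between times the estimated correlation left 0 lists in con 2 vs 0 h (2 with the preset correlation), 0 in GA effect 2 minus 0 h (3), 0 in GA effect 8 minus 4 h (1), 2 in con 8 vs 4 h (5), 3 in con 24 vs 12 h (8), 2 in GA effect 24 minus 12 h (6). Leaving out each well of the groups of 5 in turn gave 157 to 288 genes in GA vs con over the mean (251 with all), 4 to 26 in GA vs con at 8 h (9), 69 to 100 in IL6andGA vs IL6 over the mean (98), 0 to 1 in IL6andGA vs IL6 at 8 h (0), 16 to 28 in the interaction (23) and 1 to 13 in the GA effect from 4 h to 8 h (11).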

Other observations

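The tests of IL6R, of the synthetase groups and of the wells of IL6andGA against GA were chosen only after the result was seen.

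Apoptosis and p53 genes moved with GA in the presence of IL6. At 12 h 3 of 12 apoptosis and cell death genes rose over IL6 alone (4 adjusted over the list alone), the BH3-only gene PMAIP1 (NOXA) by 1.04 and the inhibitors of apoptosis BIRC2 by 0.65 and BIRC3 by 1.66, with a list median of 0.23 (adjusted p = 0.014, and adjusted p = 0.0526 with an estimated correlation). At 24 h 2 of 21 p53 targets fell (3 fell and 1 rose adjusted over the list alone), the DNA damage binding protein DDB2 by 1.15 and TP53I3 by 1.09 (median -0.15, adjusted p = 0.00655, and adjusted p = 0.0882 with an estimated correlation). Without IL6 BIRC3 rose by 1.77 at 12 h, and TSLP, an epithelial and stromal cytokine, fell by 0.73 over the mean of 2 to 24 h. The EGF family ligand EREG rose by 1.06 and stanniocalcin STC1 by 1.06 with GA and IL6 at 24 h. With the length slope as a covariate TP53I3 (adjusted p = 0.104) and EREG (0.0667) did not pass, nor did EREG without the low-count filter (0.0769).

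The wells of IL6andGA were also set against those of GA, which shows IL6 in the presence of GA. By edgeR 74 genes differed at 12 h (40 higher and 34 lower in IL6andGA) and 85 at 24 h (35 higher and 50 lower), against 766 at 0 h and 314 at 2 h. Between 12 h and 24 h 972 genes changed in IL6andGA, 365 in GA, 146 in con and 90 in IL6. These differences in number between treatments were not tested.

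Few genes differed between IL6 and con at any time other than 2 h. From 0 h to 2 h 99 genes changed in the IL6 wells and 3161 in con. Too few counts for a 2-fold response of the set is argued against by SOCS3, BCL3, JUNB, CEBPD and PIM1, known targets of the IL6 receptor. Fitted without the low-count filter, their mean log2 change over 4, 12 and 24 h was -0.02, with an upper 95% bound of 0.253. That bound takes genes measured in the same wells as independent. For PIM1 alone the upper bound was 1.185, so a 2-fold rise of that gene was not excluded. The 2 h wells were not part of this mean. A low level of the receptor cannot be told apart from other explanations: IL6R stood at 8.11 CPM in con (95% exact interval 6.78 to 9.63) and its partner IL6ST at 395.1, and a transcript level does not give the receptor protein. A response that ended before 2 h or between the times sampled, and the activity of the IL6 that was added, were not tested.

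The tRNA synthetase genes that rose with GA may be those known as ATF4 targets, a hypothesis formed after the data were seen. Of 12 cytosolic synthetases known as targets 11 rose at 12 h without IL6 and of 8 others 1 did, and the medians differed by 0.796 (0.94 against 0.14; permutation test over all 125970 splits of the 20 genes, two-sided p = 0.000222, adjusted p = 0.00037 over 5 comparisons). At 24 h 12 and 0 rose, and with IL6 12 and 0 rose at 12 h and 7 and 0 at 24 h (adjusted p = 0.000178, 7.95e-05 and 0.0249). At 4 h 0 of either group passed by edgeR, and the medians differed by 0.07 (adjusted p = 0.139). Genes are not independent replicates, and 7 of the 12 targets were seen to rise in both arms before the test.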
